A study of Homo sapiens with 20 samples.

How the data were processed

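Poly-A RNA was measured by RNA sequencing in 20 samples of human pancreatic islets from organ donors, the clusters of endocrine cells that hold the insulin-secreting beta cells. Per the labels, 10 samples were untreated and 10 were treated with the inflammatory cytokines interleukin-1β at 50 U/ml and interferon-γ at 1000 U/ml for 24 hours. The labels describe strand-specific libraries from 500 ng RNA with a mean RNA integrity number of 9.8 (SD 0.28), read as pairs of 75 bases with an average of 52.6 M reads. Reads were aligned with STAR to GRCh37, per the submitters' processing notes, and the STAR version is not given in the sources used here.

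The authors deposited 5 tables of alternative splicing events, 1 for each of skipped (cassette) exons, alternative 3 prime splice sites, alternative 5 prime splice sites, mutually exclusive exons and retained introns. Their layout is that of rMATS, and the version, settings and gene annotation are not given in the sources used here. Per the file headers, each row holds lists of inclusion and skipping junction counts for each of 2 sample sets, with 10 values in each list. The deposited inclusion level (PSI, percent spliced in) is a fraction from 0 to 1, which was recomputed here as the inclusion count over its effective length, divided by the sum of both forms treated likewise. The authors also deposited a difference of mean inclusion levels, coded as the first set minus the second, a p-value and a false discovery rate (FDR) for each event. The test behind the deposited p-value and FDR is not stated in the headers or labels.

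The headers name the sets only as sample 1 and sample 2. No header or label states which set was the untreated and which the cytokine-treated group, and the values were not used to name the sets. Results are therefore given for set 1 and set 2, and every difference computed here is set 2 minus set 1. The design written beforehand spoke of inclusion in the cytokine group. Inclusion in set 2 is given in its place, which does not assign set 2 to the treatment. That the 2 lists of 10 are the untreated and the treated samples is itself a reading of the headers and labels, and the comparisons rest on it. No header or label states whether list positions follow the replicate numbers of the labels, or which samples share a donor. The p-values measure the spread between the libraries of a set.

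Events on the Y chromosome and of the X inactivation transcript were left out. An event was tested when inclusion plus skipping counts reached 10 in at least 8 libraries of each set and its mean inclusion level over all libraries lay between 0.05 and 0.95. This left 7425 of 87370 skipped exon events, 1947 of 6692 alternative 3 prime and 1163 of 4541 alternative 5 prime splice site events, 11549 of 19920 mutually exclusive exon events and 2299 of 4607 retained intron events. For each library the log2 of inclusion over skipping counts, with 0.5 added to both, entered limma 3.58.1 in R with a trended and robust variance. P-values were adjusted by Benjamini-Hochberg within the event type. A changed event had an adjusted p below 0.05 and a difference of mean inclusion levels of at least 0.05. Coordinates are those of the deposited tables on GRCh37, counted from 1. In mutually exclusive exons the inclusion form was the exon with the lower coordinate on the plus strand and the one with the higher coordinate on the minus strand. This was checked on junctions shared with skipped exon events: the inclusion count was at least the shared junction count in 83.1% of such plus-strand and 91.2% of such minus-strand events.

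Junction coverage of a gene was taken from its best-covered skipped exon event, as length-scaled inclusion plus skipping counts per junction of 74 effective bases, with 0.5 added, scaled to the library's sum over 10053 genes with a mean of at least 20 counts, and tested with limma on the log2 scale. A fold change on this scale understates that of low genes. It is a coverage measure of genes with a cassette exon event and not a full expression table. INS, the insulin gene, took 20.2% of this coverage on average in set 1 and 19.4% in set 2, and INS-IGF2, which overlaps it, 9.77% and 9.80%. The median log2 change of all genes was 0.09 with this scaling and 0.08 with median-of-ratios scaling.

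Direction was tested with a two-sided exact binomial test, exon frame and gene lists with two-sided Fisher exact tests, and gene lists also with a logistic model holding the number of tested events and the mean junction count. List coverage was tested with limma's camera, with a preset correlation of 0.01 and with an estimated correlation. No list position block was in these list tests, so their p-values leave any pairing of libraries out. The 10 gene lists, the tests, most alternatives and the rule for named items were fixed before the data were examined. The rule took changed events, 1 per gene, ranked by the difference of inclusion level: for skipped exons the 7 highest and 7 lowest, for other types the 2 highest and 2 lowest. It also took up to 4 genes of each list with a changed event, up to 4 by adjusted p in coverage, and the 5 largest rises and 5 largest falls in coverage. List symbols were matched to gene IDs through a table of current and older symbols.

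On simulated data for the 7425 skipped exon events, the fit recovered 6.0% of events changed by 1 on the log2 scale, 56.0% of those changed by 2 and 76.0% of those changed by 4. For the 10053 genes of the coverage table it recovered 34.3% of changes of 1 and 84.8% of changes of 2. Alternatives changed the pseudocount, the filters, the minimum difference, the weights, the test and the coverage measure. Fits with the list position as a block, without the sixth library of both sets, and with acinar or stromal marker scores as covariates were chosen after seeing the data. The tests of possible reasons for a pattern had written bounds, some of them written after the result was seen. For the donor, acinar share and stromal tests, the rule that turns the value into a verdict was made stricter in the computation after the value was seen, and the written bounds were left as they were. The tests of acinar and stromal shares behind the changed events were written down after the data had been examined and before these covariates were fitted, deleted after the counts with the covariates had been seen, and then restored with the same bounds and run. The stromal covariate proved uninformative. A comparison of the coverage changes of WARS and INS, chosen after both were seen, was added, and it bears on coverage and not on exon inclusion. The analysis also used Python 3 with scipy and statsmodels.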

Results

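The data hold exon junction counts of human islet RNA in 2 sets of 10 libraries, 20 in all. The study's title names its question, which is how pro-inflammatory cytokines alter splicing in human islets. The summed junction counts of a library over the 5 tables ranged from 28.9 to 59.1 M in set 1 and from 46.0 to 72.8 M in set 2. The lowest was the sixth library of set 1, and the next lowest of that set had 44.96 M. The median count behind a tested skipped exon event was 9 in that library, against a median of 57.0 over the libraries of set 1 and 59.5 over those of set 2. Which set was cytokine-treated is not stated in the headers or labels.

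WARS, which encodes tryptophanyl-tRNA synthetase and is known to be induced by interferon-γ, held all 6 changed skipped exon events among the 7425 tested. The named one was a 68-base exon on chromosome 14 from 100841620 to 100841687, on the minus strand. Its inclusion level was 29.4% ± 10.3 (SD, n = 9) in set 1 and 94.0% ± 0.968 (SD, n = 10) in set 2, a log2 ratio difference of 5.25 (SE 0.29, limma adjusted p = 2.292e-11). Inclusion was higher in set 2 at all 9 list positions with reads in both sets, and at 9 of 10 in each of the 4 WARS events measured in all libraries. The same region gave 4 more events with exons of 68, 121 and 124 bases, which share their junctions and are not independent. Their inclusion lay between 35.3% and 37.3% in set 1 and between 93.8% and 94.9% in set 2, with an SD in set 1 of 10.5 to 23.1 percentage points. The remaining event was a 172-base exon from 100835424 to 100835595, with 86.5% ± 10.7 (SD, n = 10) in set 1 and 98.8% ± 0.644 (SD, n = 10) in set 2.

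WARS also held 6 of the 8 changed mutually exclusive exon events, 3 higher and 3 lower in set 2, which differ in their partner or flanking exons and are not independent. In the named event, the choice of the exon from 100835424 to 100835595 over that from 100820024 to 100820206 was 25.5% ± 10.3 (SD, n = 10) in set 1 and 1.83% ± 0.383 (SD, n = 10) in set 2, with limma adjusted p = 7.081e-05 and 9 of 10 positions lower. Another changed event with the same 2 exons went the opposite way, from 23.6% ± 6.44 (SD, n = 10) to 39.7% ± 5.34 (SD, n = 10), with limma adjusted p = 0.0279 and all 10 positions higher, so that no single direction holds for this choice. MDK, the growth factor midkine, chose the exon on chromosome 11 from 46403607 to 46403683 over that from 46403844 to 46404011 in 14.0% ± 4.13 (SD, n = 10) in set 1 and 25.7% ± 2.74 (SD, n = 10) in set 2. Its log2 ratio difference was 1.15 (SE 0.21, limma adjusted p = 0.0292), and all 10 positions were higher in set 2. IRF3, a transcription factor of the antiviral response, chose the exon on chromosome 19 from 50167931 to 50168103 over the adjoining one from 50167700 to 50167930 in 85.8% ± 5.53 (SD, n = 10) and 71.7% ± 7.02 (SD, n = 10). Its adjusted p was 0.0417 in limma, and all 10 positions were lower in set 2. With the acinar marker score as a covariate, chosen after seeing the data, the log2 ratio difference of MDK went from 1.15 (SE 0.21) to 1.13 (SE 0.26, adjusted p = 0.552) and that of IRF3 from -1.12 (SE 0.21) to -0.87 (SE 0.25, adjusted p = 0.853). Both calls also ended with the list position as a block (adjusted p = 0.12 and 0.249), and that of the WARS event by the rank test (adjusted p = 0.414).

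Retention of 3 introns was higher in set 2. In NUMA1, which encodes a protein of the mitotic spindle poles, the intron on chromosome 11 from 71718482 to 71719733 was retained in 14.2% ± 6.77 (SD, n = 10) in set 1 and 40.2% ± 8.09 (SD, n = 10) in set 2, with limma adjusted p = 0.0002. In DGKZ, a diacylglycerol kinase, the intron on chromosome 11 from 46400787 to 46401018 was retained in 12.2% ± 3.02 (SD, n = 10) and 25.6% ± 4.20 (SD, n = 10), with limma adjusted p = 0.000635. DGKZ lies outside the naming rule and was named after its values were seen. Both introns were higher in set 2 at all 10 positions. The third event lay in HSD17B7P2, a pseudogene that can share reads with its parent gene and is uncertain. The deposited coordinates give it a gap of 1 base on chromosome 10 at 38654545, counted as retained in 23.3% ± 15.8 (SD, n = 9) and 75.3% ± 12.5 (SD, n = 10), with limma adjusted p = 0.00172.

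Of the 1163 alternative 5 prime splice site events, 1 changed, in C7orf49. Use of the longer exon on chromosome 7 from 134853497 to 134853812, over a form that starts at 134853501, was 4.79% ± 3.70 (SD, n = 10) in set 1 and 32.7% ± 11.002 (SD, n = 10) in set 2, with limma adjusted p = 0.00051 and all 10 positions higher. None of the 1947 alternative 3 prime splice site events passed in limma (0 changed, lowest adjusted p = 0.663). At an unadjusted p under 0.05 there were 68, or 3.49% of those tested. The rank test called 1 event of this type, the fit with precision weights 0, and the authors' deposited FDR 130.

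Further events passed at least 2 of 5 other tests (precision weights, the rank test, and fits with the list position as a block, without the sixth libraries, or both) and not the limma fit given above. There were 8 such events, and both this rule and the 4 named here were chosen after the values were seen. CD44, a cell surface receptor for hyaluronan with many variable exons, included the exon on chromosome 11 from 35229652 to 35229753 at 72.1% ± 12.4 (SD, n = 10) in set 1 and 50.6% ± 12.4 (SD, n = 10) in set 2. It was lower in set 2 at all 10 positions, with adjusted p = 0.556 in the limma fit. The adjusted p was 0.0319 with the position as a block and 0.00672 with the block and without the sixth libraries. It was 0.676 with weights, 0.333 by the rank test and 0.375 without the sixth libraries and with no block. SPATS2L included the exon on chromosome 2 from 201248590 to 201248740 at 3.46% ± 0.837 (SD, n = 9) and 9.75% ± 2.77 (SD, n = 10). Its exact rank test gave adjusted p = 0.0322 against 0.949 in limma and 0.638 with the block. The adjusted p was 0.00307 with precision weights, 0.0171 without the sixth libraries and 0.0345 with the block and without them. FXYD2, a regulatory subunit of the sodium pump, chose the upstream exon of its pair at 25.1% ± 10.1 (SD, n = 10) and 50.7% ± 14.1 (SD, n = 10). Its adjusted p was 0.0208 with precision weights and 0.207 without, 0.179 by the rank test and 0.0597 with the block. Without the sixth libraries it was 0.0421, and 0.0365 when the block was also used. NT5C3A, a nucleotidase, chose that of its pair at 10.996% ± 5.94 (SD, n = 10) and 25.3% ± 4.56 (SD, n = 10). Its adjusted p was 0.0394 with precision weights and 0.324 without, 0.0796 by the rank test and 0.224 with the block. Without the sixth libraries it was 0.0114, and 0.0402 when the block was also used.

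**Figure D1:**
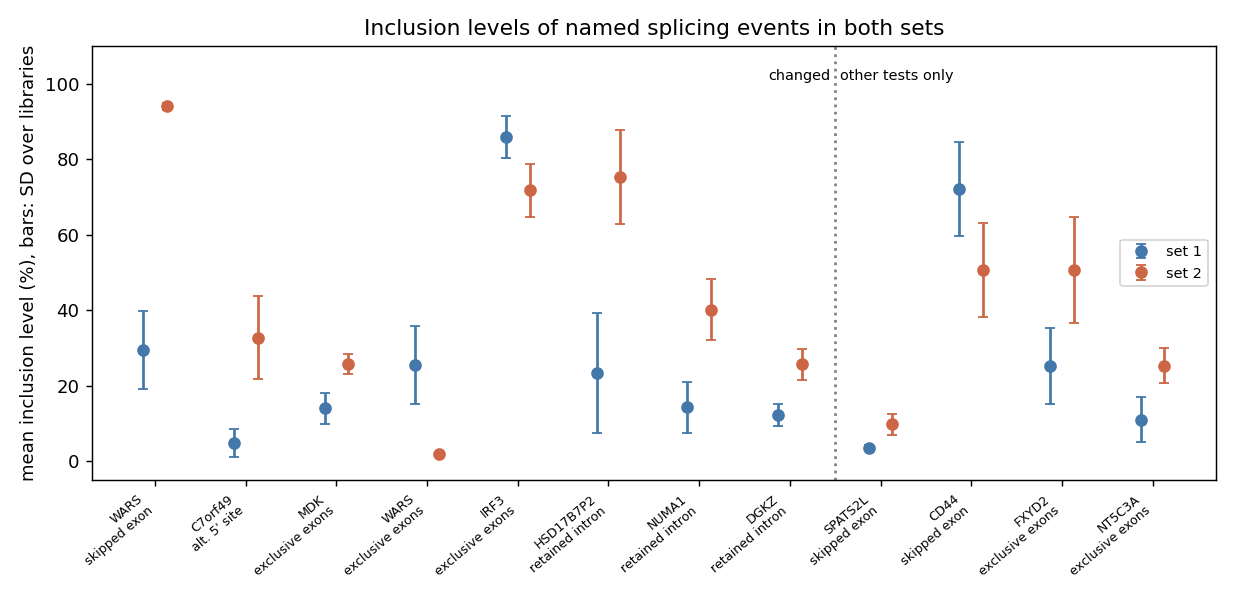
Mean inclusion level in percent (vertical axis, bars are the SD over up to 10 libraries) of named splicing events in set 1 and set 2. The WARS skipped exon lies at 29.4% and 94.0%, and the 4 events right of the dotted line passed other tests only.

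All 6 changed skipped exon events had higher inclusion in set 2 (exact binomial p = 0.0312), but they overlap in 1 gene and are not independent. Of the changed mutually exclusive exon events 4 of 8 were higher (exact binomial p = 1), and of the retained introns 3 of 3 (exact binomial p = 0.25). Without the sixth libraries 12 of 20 changed mutually exclusive exon events were higher, and 17 of 21 when the list position was also a block. With precision weights 11 of 14 changed skipped exon events were higher. The 4 distinct exons among the changed skipped exon events included 0 with a length that is a multiple of 3, against 3125 of 6508 other tested exons (48.0%, Fisher exact p = 0.126). All 4 lie in WARS and some overlap. A share of 0 is the lowest possible, so with 4 exons the test could not pass on that side and decides nothing. Among exons called by the authors' deposited FDR the share with a length that is a multiple of 3 was 47.4% of 801, against 48.1% of the rest (Fisher exact p = 0.763).

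Genes of the list of interferon response and antigen presentation held changed events more often than other genes. Of its 58 tested genes 2 had one, WARS and IRF3, against 7 of all 7330 tested genes (Fisher exact adjusted p = 0.0126). In the logistic model with event number and count the odds ratio was 32.5 (95% interval 3.74 to 282). Both values rest on 2 genes, and the IRF3 call ended with the list position as a block (adjusted p = 0.249) and with the acinar score as a covariate (adjusted p = 0.853), which would leave 1 of 58. Adjusted over the list alone, 23 of its 226 events passed, against 13 over all events. The 13 are overlapping WARS events and 1 IRF3 event, and the number of genes behind the 23 is not given. Adjusted over the list alone, 1 event of the exocytosis list and 1 of the list of markers of other cell types passed, and 0 in the other 7 lists, where 0 passed over all events in limma. The rank of lists under the authors' deposited FDR was led by the same list, with 19 of 58 genes called (32.8%) against 20.9% of other genes. That difference did not pass by Fisher's exact test (adjusted p = 0.347) and passed in the logistic model (odds ratio 2.96, 95% interval 1.62 to 5.42, adjusted p = 0.00426). By the authors' deposited FDR, 28.6% of splicing regulator genes (30) had a called event, and 7 of 27 genes of islet hormones and beta cell identity, neither past Fisher's exact test (adjusted p = 0.347 and 0.699).

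In the authors' deposited table, FDR below 0.05 with an inclusion difference of at least 0.05 was met by 3242 skipped exon events, and 2233 of them had a difference of at least 0.1. The authors' deposited tables gave 394 and 248 alternative 3 prime, 286 and 183 alternative 5 prime, 1568 and 749 mutually exclusive exon and 299 and 170 retained intron events at the same limits. Inclusion was higher in set 2 in 53.4% of the deposited skipped exon calls, 60.2% of the mutually exclusive exon calls and 44.1% of the retained intron calls. All 18 events that passed the limma fit were among the deposited calls. Of the deposited skipped exon calls, 72.4% failed the count filter, and the median call had 4.85 counts per library. Among the 827 deposited skipped exon calls that passed the count and inclusion filters, 231 had an unadjusted limma p under 0.05.

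Junction coverage of many genes differed between the sets. Of 10053 genes, 711 had higher and 529 had lower coverage in set 2. The largest rises were those of CXCL10, CXCL9 and CXCL11, chemokines that attract T cells, of IDO1, which degrades tryptophan, and of LGALS17A, a galectin gene copy that can share reads with its family and is uncertain. CXCL10 had 5.60 junction counts per library in set 1 and 16292 in set 2, a log2 change of 12.18 (SE 0.59, limma adjusted p = 7.175e-13). CXCL9 rose by 11.63 (SE 0.65), CXCL11 by 11.38 (SE 0.53) and LGALS17A by 10.40 (SE 0.34). IDO1 had 10 and 10445 counts per library, a log2 change of 10.35 (SE 0.48). These genes lay near 0 in set 1, with no read in 4 libraries for CXCL10 and CXCL11, in 5 for CXCL9 and in 9 for LGALS17A, so that the size of their changes depends on the pseudocount. When the coverage was summed over all skipped exon events of a gene, 713 genes rose and 937 fell. With the list position as a block, chosen after seeing the data, 1569 rose and 1681 fell, so that the balance of rises and falls depends on the fit.

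Of 99 measured genes of interferon response and antigen presentation, 86 rose and the other 13 did not pass. The list's median log2 change was 3.21 and its camera adjusted p was 0.00083 with an estimated correlation. Adjusted over the list alone, 95 passed. WARS rose by 6.03 (SE 0.12, log2), from 995 to 69067 counts per library. PSMB9, a subunit of the immunoproteasome, rose by 5.10 (SE 0.19), and TAP1, a peptide transporter of antigen presentation, by 5.26 (SE 0.21). GBP5, an interferon-induced GTPase, had 0.4 counts per library in set 1 and 1950 in set 2. HLA-B rose by 2.36 (SE 0.27), and HLA genes can share reads between family members, so their values are uncertain.

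In the list of interleukin-1 and NF-kB signalling, 38 of 64 genes rose and the other 26 did not pass, with a median log2 change of 1.60. The camera call was lost with an estimated correlation (adjusted p = 0.0934). The camera tests of all lists left the list position out, so a lost call is not evidence of no change. NOS2, the inducible nitric oxide synthase, had 0.7 counts per library in set 1, with 4 libraries at 0, and 522 in set 2. NFKBIA, the inhibitor of NF-kB, rose by 3.03 (SE 0.21), CD40 by 3.12 (SE 0.20) and RIPK2 by 3.59 (SE 0.26). Adjusted over the list alone, 42 genes passed.

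Apoptosis genes rose in 18 and fell in 3 of 52 cases, 24 passing when adjusted over the list alone. The camera adjusted p was 5.18e-05 with the preset and 0.374 with an estimated correlation. The members that rose included CFLAR, an inhibitor of death receptor signalling, at 2.28 (SE 0.19), the death receptor FAS at 3.62 (SE 0.49), CASP4 at 2.10 (SE 0.23) and GSDMD, which forms membrane pores, at 1.62 (SE 0.23). PDCD4, HTRA2 and BAD fell by 0.83, 0.53 and 0.42 (SE 0.18, 0.17 and 0.14), named after their values were seen. Of 62 genes of endoplasmic reticulum stress 6 rose, 5 passing when adjusted over the list alone. Their camera adjusted p was 0.0173 with the preset and 0.579 with an estimated correlation. ATF3, a stress-induced transcription factor, rose by 2.35 (SE 0.28) and ERO1L, an oxidase of disulfide formation, by 1.88 (SE 0.32). DERL1 and PDIA6, which act in the endoplasmic reticulum, rose by 0.67 (SE 0.16) and 0.46 (SE 0.12). With median-of-ratios scaling 10 of these 62 rose and 2 fell, and with the list position as a block 18 rose and 5 fell. The block gave 25 rises and 5 falls among the apoptosis genes.

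Of 39 measured genes of islet hormones and beta cell identity, 2 rose and 4 fell, the same number of 6 passing when adjusted over the list alone. The camera adjusted p was 0.0138 with the preset and 0.395 with an estimated correlation. G6PC2, an islet glucose-6-phosphatase subunit, fell by 2.00 (SE 0.44, log2), from 1535 to 368 counts per library. MNX1, a beta cell transcription factor, fell by 1.12 (SE 0.23) and KCNK16, a potassium channel, by 1.45 (SE 0.42). RFX3 rose by 1.68 (SE 0.46). INS showed a log2 change of -0.08 (SE 0.21, limma adjusted p = 0.855), GCG, the glucagon gene, -0.34 (SE 0.28, adjusted p = 0.493) and IAPP, the amylin gene, -0.95 (SE 0.40, adjusted p = 0.132). With the list position as a block, chosen after seeing the data, 4 of these 39 genes rose and 16 fell. Of 18 islet autoantigens, G6PC2 fell while GAD1, a glutamate decarboxylase, rose by 2.66 (SE 0.67) and CHGA, chromogranin A, by 0.53 (SE 0.17). GAD1 had 23.4 counts per library in set 1, with 2 libraries at 0. CHGA did not pass with median-of-ratios scaling (adjusted p = 0.0577), under which 1 autoantigen rose and 4 fell. ICA1 had a log2 change of -0.39 (SE 0.13, adjusted p = 0.0597). With the block 2 autoantigens rose and 11 fell. Adjusted over the list alone 10 passed, and the list's camera adjusted p was 0.011 with the preset and 0.275 with an estimated correlation.

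Of 71 genes of exocytosis and calcium entry 3 rose and 6 fell, 10 passing when adjusted over the list alone (camera adjusted p = 0.948 with the preset and 0.987 with an estimated correlation). In the fit with the position as a block 14 of them rose and 12 fell. RAB27A and RAB3A, small GTPases of secretory granules, went in opposite directions, with log2 changes of 1.07 (SE 0.17) and -1.39 (SE 0.28). KCNH2, a potassium channel, fell by 1.03 (SE 0.18) and CACNA1C, a voltage-gated calcium channel, by 0.63 (SE 0.18). CACNA1C did not pass when coverage was summed over events (adjusted p = 0.0672). Of 34 type 1 diabetes candidate genes 10 rose and 2 fell, 15 passing when adjusted over the list alone (camera adjusted p = 0.00929 with the preset and 0.275 with an estimated correlation). IFIH1, a sensor of viral RNA, rose by 2.66 (SE 0.28), GSDMB rose by 2.69 (SE 0.43), and CTSH, the protease cathepsin H, fell by 2.33 (SE 0.36). GSDMB had 6.4 counts per library in set 1, with 1 library at 0. With the block 15 of the 34 rose and 5 fell. Several members of this list are also in the interferon list.

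Of 121 measured splicing regulators 3 rose, 1 passing when adjusted over the list alone. The median log2 change was 0.19 (camera adjusted p = 0.0642 with the preset and 0.715 with an estimated correlation). WTAP, a subunit of the RNA methylation complex, rose by 1.57 (SE 0.21), the RNA-binding protein gene QKI by 1.01 (SE 0.27) and CCNL1, a cyclin, by 0.67 (SE 0.19). CCNL1 did not pass when coverage was summed over events (adjusted p = 0.198). RBFOX3 had a log2 change of -1.24 (SE 0.51, adjusted p = 0.129). With the list position as a block 18 regulators rose and 3 fell.

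**Figure D2:**
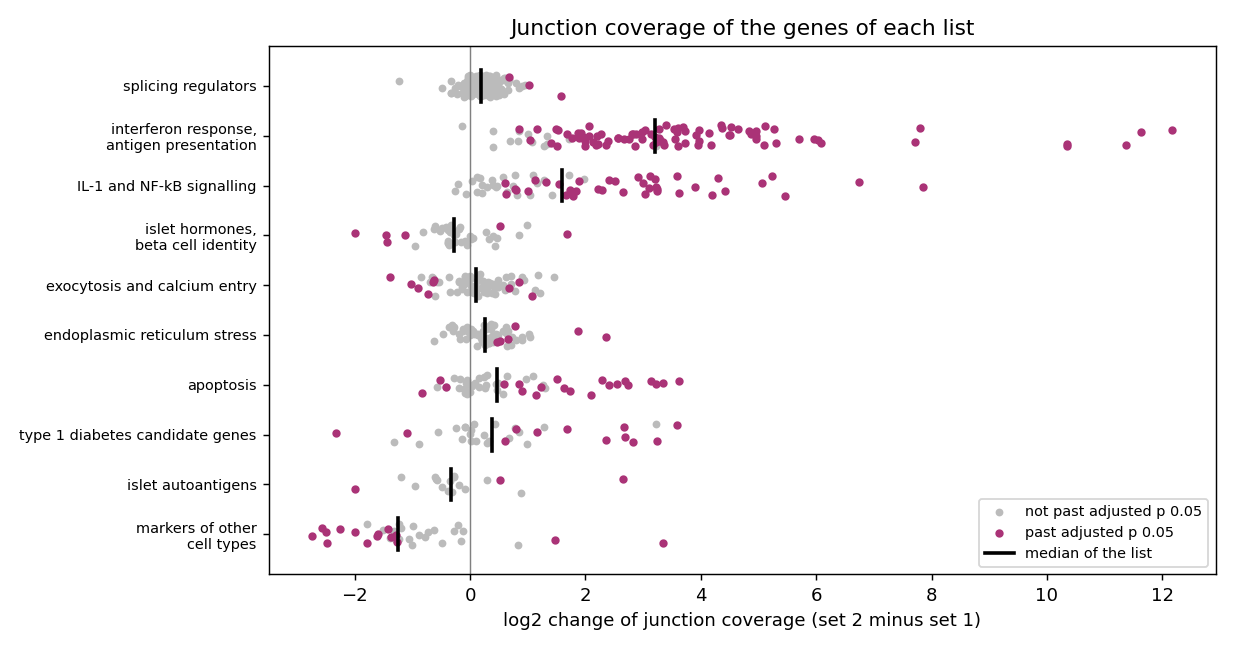
Log2 change of junction coverage (horizontal axis, set 2 minus set 1) of each measured gene of the 10 lists, with the median of a list as a black bar. Points of interferon response and antigen presentation lie around a median of 3.21, and those of splicing regulators around 0.19.

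Markers of other cell types had lower coverage in set 2 in 13 of 36 cases and higher coverage in 2, with 20 passing when adjusted over the list alone. Their median log2 change was -1.25 (camera adjusted p = 1.27e-07 with the preset and 0.275 with an estimated correlation). Of 15 acinar genes, which encode digestive enzymes and related proteins, 9 fell, and the mean log2 change was -1.55. REG1A and REG1B fell by 2.5 (SE 0.57) and 2.57 (SE 0.56), and both belong to a family that can share reads. The duct genes CFTR and TSPAN8 fell by 2.48 (SE 0.57) and 2.73 (SE 0.64), and the endothelial genes VWF and ESAM by 2.26 (SE 0.63) and 1.26 (SE 0.35), all 4 named after their values were seen. Of 11 stromal genes 1 passed, PDGFRA, which rose by 3.34 (SE 0.70), and the macrophage gene CD68 rose by 1.47 (SE 0.31). PDGFRA had 13.6 counts per library in set 1, with 3 libraries at 0, so the size of its rise depends on the pseudocount. The acinar score was lower in set 2 at all 10 list positions. With the position as a block 3 of the 36 markers rose and 28 fell.

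**Figure D3:**
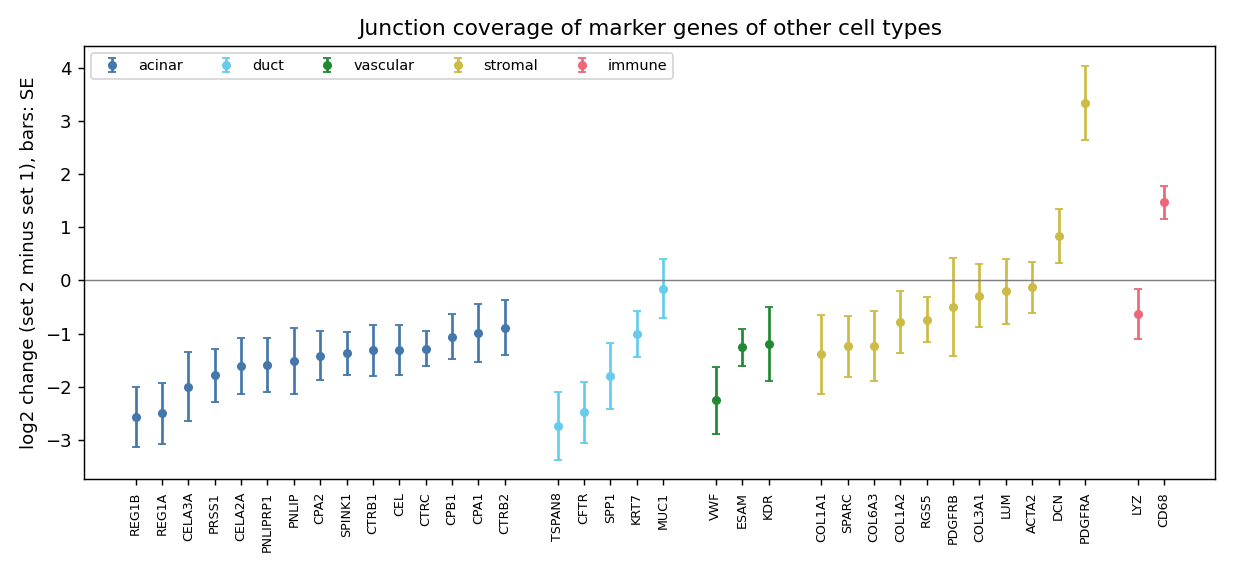
Log2 change of junction coverage (vertical axis, set 2 minus set 1, bars are the SE of the limma fit) of the measured marker genes of acinar, duct, vascular, stromal and immune cells. All 15 acinar genes lie below 0, while PDGFRA lies at 3.34.

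The largest falls in coverage were those of MMP11, a matrix metalloproteinase, ADH1C, an alcohol dehydrogenase, SERPINA5, a protease inhibitor, GSTA1, a glutathione transferase, and ANXA9, an annexin. MMP11 fell by 4.71 (SE 0.72, log2), from 309 to 12.8 counts per library, with limma adjusted p = 6.425e-05. ADH1C fell by 4.42 (SE 0.81), SERPINA5 by 4.29 (SE 0.62), GSTA1 by 4.22 (SE 0.64) and ANXA9 by 4.16 (SE 0.52). Each was lower in set 2 at all 10 list positions. ADH1C had no read in 3 libraries of set 2, and MMP11 and ANXA9 in 1. ADH1C and GSTA1 have close paralogs with which they can share reads and are uncertain. Without the sixth library of both sets, chosen after seeing the data, 1018 genes rose and 984 fell.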

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

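Tests of the donor, of few junction reads, of the sixth libraries behind the deposited calls, of the scaling and of the stromal genes were chosen after the result was seen. For the donor, acinar and stromal tests, the rule that turns the value into a verdict was made stricter in the computation after the value was seen, each toward leaving the question open, while the written bounds stayed as they were. Of 124 groups of values, 21 had a library farther from the rest than Dixon's ratio of 0.466 (10 libraries) or 0.493 (9 libraries) allows, while chance gives about 1 in 20 groups. Of these libraries 6 were the sixth of a set. The gap divided by the range was 0.531 for the summed junction counts and 0.483 for the vascular marker score of the sixth library of set 1. In inclusion levels of that library it was 0.514 for the WARS exclusive exons, 0.551 for IRF3 and 0.66 for NUMA1, which was also highest in the sixth library of set 2 at 0.566. The WARS skipped exon had a ratio of 0.541 in set 1 in another library. In log2 junction coverage the first library of set 1 was lowest for MMP11 (0.748), ANXA9 (0.658), MNX1 (0.623), GSTA1 (0.622), SERPINA5 (0.613), CTSH (0.591), RAB3A (0.496) and REG1A (0.493). The first library of set 2 was lowest for HLA-B (0.719), GSDMD (0.578), KCNK16 (0.523) and CXCL9 (0.471). LGALS17A was highest (0.696) and CHGA lowest (0.481) in the tenth library of set 1.

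The sixth library of both sets stood apart in inclusion levels. Lower junction read depth is argued against, because after the other libraries of set 1 were thinned to its counts its deviations still had an SD 2.18 times the highest of the others (2.81 against 1.29 on the log2 scale). Among events with a median inclusion level between 0.2 and 0.8 and at least 50 counts, 17.6% had an inclusion level under 0.05 or over 0.95 in this library, 10.4 times the highest share in the rest of set 1 (1.70%). In set 2 the sixth library had 3.61% and the highest other 1.43%. Few starting RNA molecules may explain such all-or-none levels, as a hypothesis. Splicing particular to the donor stays open, since the correlation of the deviations of both sixth libraries was 0.126 (95% bootstrap interval 0.101 to 0.15), against a lowest of 0.128 and a median of 0.197 at the other positions.

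Many more skipped exon events passed the deposited FDR than the limma fit over libraries, 3242 of 87300 against 6 of 7425. On the same 7425 events the counts were 827 against 6. The sixth libraries as the main reason are argued against, since 8.5% of the deposited calls lost at least 50% of their difference without them. Few junction reads as the explanation for most calls stay undecided, though 72.4% of them failed the count filter. Most events fail the filters: 7425 of all 87300 passed the count and inclusion range filters, against 827 of the 3242 calls. Calls were thus more frequent inside these filters than among all events. The calls that failed did not enter the limma fit. Their share was not set against that of all events that fail the count filter alone. For the 827 calls that passed this filter and the inclusion range filter, the spread between libraries of a set may matter. The variance of inclusion levels within sets had a median of 3.38 times its counting variance, and 2.43 times without the sixth libraries. The second value lies under the written bound. Separate samples usually vary by more than counting alone, so these values decide little. No biological explanation was tested.

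Acinar and duct marker genes had lower coverage in set 2, with a mean log2 change of -1.55 over 15 acinar genes. The choice between 2 scalings of the libraries did not matter, since median-of-ratios scaling gave -1.56. The 2 scalings were close, with a median log2 change of all genes of 0.09 and 0.08, so this is a weak test of scaling. A lower share of acinar cells and regulation within them cannot be told apart here: the changes ranged from -2.57 to -0.89, and the permutation p that they differ from each other was 0.0621. A lower share of every cell type that is not endocrine also stays open. The mean log2 change was -1.63 over 5 duct genes and -1.57 over 3 vascular genes, all of them lower in set 2. It was 0.42 over 2 immune genes, 1 of them lower. The stromal mean was -0.21 (95% bootstrap interval over 11 genes -0.84 to 0.63) against -1.80 to -1.32 for acinar genes. However, 9 of the 11 stromal genes were lower in set 2, with a median of -0.495. PDGFRA, with no read in 3 libraries of set 1, rose by 3.34, and the SD over stromal genes was 1.34. The treatment itself, a biological difference that the design names, stays open and untested as a reason for these falls. The labels do not tie the sets to it. In coverage, 86 of 99 genes of interferon response and antigen presentation rose in set 2 and 0 fell. Of 64 genes of interleukin-1 and NF-kB signalling 38 rose and 0 fell. If the 2 sets are the untreated and the treated samples, these values argue against set 1 as the cytokine-treated set.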

How the results depend on the processing

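Changed skipped exon events rose from 6 to 16 without the inclusion range filter, 19 with no filter and 14 with precision weights. The mutually exclusive exon count of 8 became 13 with no filter and 3 by the rank test. The alternative 5 prime count of 1 became 2 with weights, and the alternative 3 prime count of 0 became 1 by the rank test. By the deposited FDR on the tested events the counts were 827 skipped exon, 130 alternative 3 prime, 105 alternative 5 prime, 993 mutually exclusive exon and 116 retained intron events. The share of changed skipped exon events higher in set 2 was 68.4% with no filter, 78.6% with weights and 100% of 5 events by the rank test, none of them past the binomial threshold. The interferon list had 19 genes by the deposited FDR and did not pass Fisher's exact test. Of the deposited calls, 896 skipped exon, 135 alternative 3 prime, 106 alternative 5 prime, 1001 mutually exclusive exon and 119 retained intron events passed the count filter. The cause of these differences was not tested, except that fewer or more events enter where a filter changes.

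The following settings were chosen after seeing the data. With the list position as a block, a paired fit, there were 10 changed skipped exon events (80% higher in set 2) and 3250 genes with changed coverage. The paired fit without the sixth libraries gave 15 (73.3% higher), 21 mutually exclusive exon events and 4312 genes. Without the sixth libraries and with no block there were 20 mutually exclusive exon events, 2 alternative 5 prime events and 2002 genes. With the acinar score as a covariate 3 mutually exclusive exon events remained in the count. Libraries at the same list position deviated together in skipped exon ratios (correlations 0.126 to 0.595, each library correlating best with its own position) and in coverage (0.387 to 0.819), but in retained introns 4 of 10 positions exceeded 0.1. Libraries are thus paired by position in these values, but no label states what a position stands for, and a fit by the labels' own numbers was not run. The main fits, the camera tests and the permutation tests of inclusion levels leave this pairing out. A result that did not pass in them is therefore not evidence of no change. All 1240 genes of the coverage result were also called with the block.

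Of 387 values of named coverage genes under other settings, 377 kept their direction and side of the threshold, 4 lost and 6 gained the call, and none turned. Of 95 values of named events 88 kept both and 7 lost the call. Many smaller changes can be missed, since the simulated recovery of a log2 change of 1 in skipped exons was 6.0%, and depth was not varied in that simulation.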

Other observations

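These observations were all chosen after seeing the data, apart from the other splits of the libraries and the test of deposited calls against coverage, and the tests of acinar and stromal shares were run after related counts were seen. With the list position as a block and without the sixth libraries, more islet genes passed in coverage. Of the 39 genes of islet hormones and beta cell identity 6 rose and 23 fell, and of 18 islet autoantigens 3 rose and 13 fell. Of 71 exocytosis and calcium entry genes 16 rose and 16 fell, and of 62 genes of endoplasmic reticulum stress 24 rose and 8 fell. Of 36 markers of other cell types 3 rose and 29 fell.

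The median inclusion level over all tested events of a type was close in both sets. For retained introns it was 9.66% ± 0.363 (SD, n = 10) in set 1 and 9.76% ± 0.371 (SD, n = 10) in set 2, with a two-sided permutation p of 0.574 and an adjusted p of 0.842 over 5 event types. For skipped exons it was 80.6% ± 7.001 and 78.9% ± 2.22 (SD, n = 10), with a permutation p of 0.703. Without the sixth library of both sets the difference for skipped exons went from -1.65 to 0.099 percentage points (permutation p of 0.899). The lowest of the 5 permutation p-values was 0.473, for mutually exclusive exons. These tests leave the list position out. The median was higher in set 2 at 8 of 10 positions for mutually exclusive exons and for retained introns, and at 6 of 10 for each other type.

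Events called at the deposited FDR lay somewhat more often in genes whose coverage changed. Of 793 genes with changed coverage 189 held such an event among the tested ones (23.8%), against 1330 of 6295 other genes (21.1%). In a logistic model with the number of tested events and the mean junction count, the odds ratio was 1.39 (95% interval 1.14 to 1.68). As a hypothesis, a change in the level of a gene may go with a change of its transcript structure, though isoforms with different coverage of the measured junctions would give the same relation.

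Whether any grouping of the libraries would give such counts was tested by drawing 99 other splits into 10 and 10. The real split gave 6 changed skipped exon events against at most 1 in other splits, and 8 against 0 mutually exclusive exon events. It gave 3 against 1 retained intron events and 1240 against 1 genes in coverage. For these 4 results only the real split of 100 gave as many, which is the lowest share this test can give. For the alternative 5 prime splice site event, 2 of the 100 splits, the real one included, gave as many as 1. Another split thus gave the same count as the real one. For alternative 3 prime events the real count was 0 and the highest other 0, so that all 100 splits give as many by construction and the count says nothing about chance. Among splits that part the list positions as the real one does, the highest other was 5 skipped exon events and 805 genes. These came closer to the real 6 and 1240, and neither kind of split excludes chance.

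A different share of acinar or stromal cells was tested as the reason for the changed skipped exon events, all in WARS. With the acinar score as a covariate the median ratio of the log2 ratio difference to that without was 1.07 (95% bootstrap interval over 6 overlapping events 1.03 to 1.14), and with the stromal score, the covariate for a lower share of stromal cells in set 2, it was 1 (0.99 to 1). The acinar interval is over overlapping events of 1 gene and holds no spread between libraries. In the named WARS event the log2 ratio difference was 5.48 (SE 0.36) with the acinar score and 5.25 (SE 0.29) without. That argues against a lower acinar share as the whole reason for the WARS skipped exon events. Other events are not covered, and score and set are hard to part, since the score was lower in set 2 at all 10 positions. The mean stromal score differed little between the sets (-0.21, 95% bootstrap interval over genes -0.84 to 0.63), though it was lower in set 2 at 8 of 10 list positions and in 9 of 11 genes. This covariate could therefore move little and decides nothing by itself. A lower stromal share would raise genes of the remaining cells alike, but the log2 coverage change of WARS exceeded that of INS by 6.11 (SE 0.24). The 2 genes thus did not rise alike. Both values were known beforehand, so the comparison could not fail and describes the 2 genes without testing the stromal share. The comparison does not test exon inclusion, so a lower stromal share behind the changed inclusion stays open. Both tests were written down after the data had been examined and before these covariates were fitted, deleted once the counts with the covariates had been seen, and run later with the same bounds. The comparison of WARS with INS was chosen after both values were seen.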
